A study of Mus musculus with 25 samples.

How the data were processed

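Expression was measured in 25 samples of sciatic nerve macrophages from C57BL/6 mice, 1 microarray each, of total RNA. The labels put them in 8 groups: steady state (3 arrays), MHCII high and MHCII low macrophages at day 1.5 (3 and 3), day 5 (3 and 3) and day 10 (4 and 3) after sciatic nerve crush, and macrophages at day 37 (3), for which the labels give no MHCII split. Group and replicate number were taken from each sample's title. The labels do not describe the sort, the number of animals per sample, or any batch.

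The deposited values were on the log2 scale, and per the submitters' processing notes the authors used RMA, which corrects background, quantile-normalizes arrays and summarizes the probes of a probe set, and limma; no versions or genome build are given in the sources used here. The authors' values were present in 2 tables, a table of the 25 samples and a larger table of 47 arrays. For the 25 samples they were the same in all probe sets (largest difference 0), and the 22 columns of the other arrays were not used. Values were used as deposited. Quantile normalization gives all arrays nearly the same distribution, so a change in the total RNA of a cell cannot be seen, and background correction compresses differences of dim probe sets.

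Probe sets were named from the platform annotation: 21789 had exactly 1 gene symbol, 1621 had several and 12146 had none, and probe sets with several or none were not named. Of the 21789, 21698 matched a gene by Entrez number in a table of the GRCm38.p6 assembly, which changed 0 symbols; no coordinates were used. Where a gene had several probe sets (999 genes) the one with the highest mean over the 25 arrays was kept. Of 19938 genes, the 11725 with a log2 value of at least 6 in at least 3 arrays were tested.

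Tests used limma 3.58.1 in R 4.3.3, with tables handled by the data.table package, version 1.17.8. A single fit held all 25 arrays with a mean per group, so that all groups share an estimate of each gene's spread (17 residual degrees of freedom), followed by contrasts and eBayes with default settings, two-sided, with Benjamini-Hochberg adjustment over the genes of each contrast. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, a 2-fold change. There were 12 contrasts: days 1.5, 5, 10 and 37 against steady state, MHCII high against low at days 1.5, 5 and 10, day 5 against 1.5, 10 against 5 and 37 against 10, and the change of the MHCII difference from day 1.5 to 5 and from day 5 to 10. For days 1.5, 5 and 10 the MHCII high and MHCII low means weighed equally, whatever their share of the cells. Errors of log2 fold changes are standard errors of the fit, and errors of group values are standard deviations over arrays.

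Whether replicate numbers pair the MHCII high and low arrays of a day was checked by correlating their deviations from the group means. At day 5 all 3 same-numbered pairs correlated above 0.1 (0.18 to 0.37), at day 1.5 2 of 3 (0.06 to 0.14) and at day 10 0 of 3 (-0.07 to 0.03). Each MHCII low array was closest to the high array of its own number at days 1.5 and 5 (3 of 3 each), against 0 of 3 at day 10. At day 10 the highest correlation was that of high replicate 4 with low replicate 3 (0.34). The numbers were taken to pair the arrays at day 5 only. The main fit held no block for these pairs. Where it averaged the day 5 arrays against steady state, day 1.5 or day 10, it treated them as independent. If paired arrays share a source, the errors and p-values of those comparisons are too small, and this was not tested. Pairs at day 1.5, or under other numbers at day 10, were not excluded. This pairing comes from the data, and the labels name no shared animal.

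A set of 28 gene lists (pathways, macrophage states and markers of other cell types of nerve and blood) was written from textbook knowledge. Lists with at least 3 tested genes were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and contrasts; camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with others, were run beside it. Each list's p is that of camera at the preset correlation unless named otherwise, and a list's call held with an estimated correlation wherever no other p is given beside it, in the fit without the block; for MHCII high against low at day 5 the p with the block is given where that ends the call. The count of called members is given over all genes tested and with p-values adjusted over the list alone.

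Named genes followed a fixed rule. For days 1.5 to 37 against steady state these were the 8 largest rises and 8 largest falls among called genes whose arrays all lay beyond every steady-state array; for MHCII high against low, the 6 largest in each direction among genes without overlap, leaving out the 4 sort genes; between days, the 5 largest in each direction without overlap; for the change of the MHCII difference, the 5 largest; and up to 4 members of each list described, with called members first. The sort genes and sex-linked genes were always given, and unnamed gene models were counted but not named. Csf1r, Adgre1, Itgam, Cd3e, Col1a1 and Col3a1 were, beside members in the closing section, named after their values were seen. Groups, contrasts, thresholds, gene lists, the naming rule and all alternatives except the 3 named next were fixed before the data were examined. The 3 alternatives added later were Y-linked transcripts as a covariate, leaving out the 7 arrays that held them (Kdm5d, Eif2s3y and Uty all above log2 6), and leaving out steady state replicate 2 and day 37 replicate 1 together. Alternatives fixed beforehand were the 47-array table, repeated quantile normalization, no filter or a floor of log2 7, the mean of a gene's probe sets, only the groups compared, trended and robust variance, array weights, a block for replicate number, other thresholds, and leaving out each array in turn.

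The code was tested on simulated data with the real genes' spreads, 11725 genes and 100 changed genes of each size per contrast. It recovered 88% (MHCII difference, day 10 against 5) to 100% (day 1.5 against steady state, among others) of genes changed by log2 1.5, and 94% (MHCII difference, day 5 against 1.5) to 100% of those changed by log2 2, with 0 to 5 false calls per contrast. Of 100 unmoved lists of 20 genes camera gave 3 an unadjusted p under 0.05. Counts of calls were set against those from other splits of the same arrays, at most 100 per comparison, and, where day 5 arrays took part, from splits that part as many of their pairs, a version added after the results were seen. For the change of the MHCII difference the planned test permuted the MHCII labels within each day; a second version, which permutes the residuals of a fit of day and subset, was added after the result of the first had been seen, since permuted labels carry the real MHCII difference into the permutations. The closing section gives the results of both.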

Results

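The data were 25 microarrays of macrophages from the sciatic nerve of C57BL/6 mice, an inbred laboratory strain, taken before injury or after the nerve had been crushed. A crush breaks the axons but leaves the nerve's sheaths in continuity, and macrophages then clear myelin and axon debris while the nerve regrows. There were 3 arrays of steady-state nerve, 3 of MHCII high and 3 of MHCII low macrophages at day 1.5, 3 and 3 at day 5, 4 and 3 at day 10, and 3 of unsplit macrophages at day 37. MHCII is the major histocompatibility complex class II, the surface molecule that presents peptides to helper T cells. Values were log2 RMA values of 1 array per sample. The mean correlation of an array with the others of its group lay between 0.942 (steady state replicate 2) and 0.985, and no arrays held identical values. The 3 steady-state arrays had the lowest values (0.948, 0.942 and 0.945), against 0.978 to 0.985 at days 1.5 and 5. As the fit shares an estimate of spread over all groups, errors of comparisons with steady state may be too small. The number of arrays limits the precision of each value, and since the labels do not say that replicates came from separate animals, the p-values measure only the spread between these samples. A gene was called when limma's adjusted p was under 0.05 and its log2 fold change was at least 1 in size, out of 11725 genes tested.

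Transcripts of the molecule that names the subsets were checked against the labels first. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 encode MHC class II chains and their chaperone, the invariant chain. At day 1.5 H2-Aa stood at 12.50 ± 0.06 (SD, n = 3) in MHCII high and 7.33 ± 0.97 (SD, n = 3) in MHCII low macrophages, against 12.91 ± 0.08 (SD, n = 3) in steady state. The low group stood at 9.56 ± 0.23 (SD, n = 3) at day 5 and 10.98 ± 0.21 (SD, n = 3) at day 10, while the high group stood at 12.70 ± 0.04 (SD, n = 3) and 12.94 ± 0.09 (SD, n = 4). High minus low differences at days 1.5, 5 and 10 were 5.17 ± 0.27, 3.14 ± 0.27 and 1.96 ± 0.25 (SE) for H2-Aa and 4.25 ± 0.12, 3.32 ± 0.12 and 2.71 ± 0.11 for H2-Ab1. They were 4.94 ± 0.16, 4.13 ± 0.16 and 3.54 ± 0.15 for H2-Eb1 and 3.47 ± 0.16, 3.08 ± 0.16 and 2.36 ± 0.15 for Cd74. All 12 passed, with adjusted p values from 1.04e-16 (H2-Ab1, day 1.5) to 5.29e-05 (H2-Aa, day 10). In steady state and at day 37, where the labels give no split, H2-Eb1 stood at 12.74 ± 0.09 (SD, n = 3) and 12.85 ± 0.18 (SD, n = 3).

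**Figure D1:**
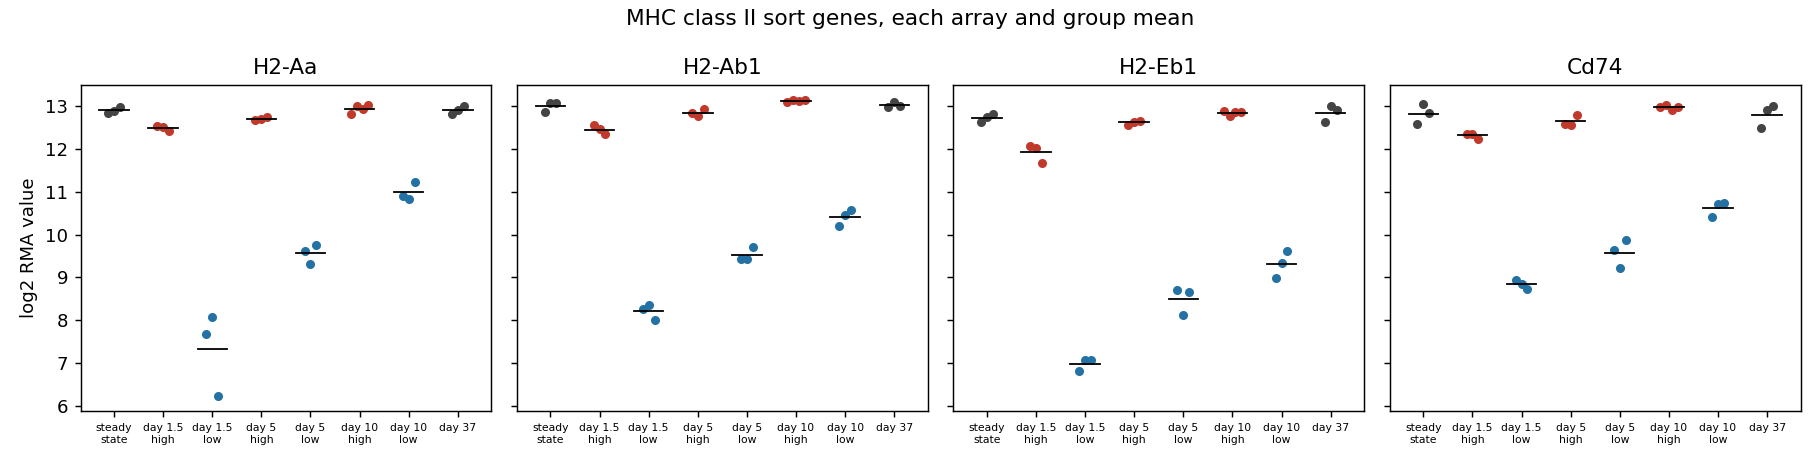
Log2 RMA values of the MHC class II sort genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 (y axis) in each of the 8 groups (x axis); each point is an array, each bar the group mean, with MHCII high in red, MHCII low in blue and unsplit groups in grey. The MHCII low arrays sit below all other arrays at each time, and their H2-Aa mean is 7.33 at day 1.5, 9.56 at day 5 and 10.98 at day 10.

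Which macrophage transcripts are present in steady state was the baseline for all later times. Genes shared by macrophages were bright there: Csf1r, the receptor for the growth factor CSF1, stood at 12.38 ± 0.34 (SD, n = 3) and Adgre1, which encodes the F4/80 antigen, at 11.70 ± 0.15 (SD, n = 3). Of 12 tested core macrophage genes 1 was called at day 1.5 (Itgam, an integrin chain, 1.32 ± 0.14, SE) and 0 at days 5, 10 and 37 by limma, with 7, 7 and 2 at an unadjusted p under 0.05. Endothelial genes gave 0 calls of 5 at any of the 4 times by limma (4, 2, 2 and 2 at an unadjusted p under 0.05 at days 1.5, 5, 10 and 37). The fibroblast list gave 1 higher and 2 lower of 8 at day 1.5, 1 lower at day 5, 1 higher at day 10, and 1 higher and 1 lower at day 37. Only 1 of 12 markers of T, B and NK cells was bright enough to be tested (Cd3e, 0 calls), and 0 of 8 mast cell markers and 0 of 8 red blood cell genes were.

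Day 1.5 after crush was compared with steady state, which asks how the macrophages of the nerve differ early after injury. The MHCII high and MHCII low groups weighed equally here and at days 5 and 10, while steady state was unsplit. For the largest rises and falls named, every array of both subsets lay beyond every steady-state array, so only their size depends on this weighing. For other genes that differ between the subsets, a different mix of subsets cannot be told apart from a change over time. Chil3, a chitinase-like protein of recruited myeloid cells, rose by 7.12 ± 0.45 on the log2 scale (SE, 6 arrays against 3), and Arg1, which breaks down arginine, by 6.61 ± 0.18. The haptoglobin gene Hp rose by 5.78 ± 0.25 and the matrix protein gene Thbs1 by 5.52 ± 0.26. Vcan, a matrix proteoglycan of monocytes, rose by 5.39 ± 0.17, the acute phase gene Saa3 by 5.31 ± 0.32, Plac8 by 5.29 ± 0.29 and Gpnmb, a glycoprotein of phagocytes, by 5.21 ± 0.27. The adjusted p values of these 8 genes ran from 4.51e-17 to 2.45e-11. The steepest falls were those of Tcim (-5.79 ± 0.29), the lectin gene Mgl2 (-5.38 ± 0.22), Gpr165 (-5.30 ± 0.22), P3h2 (-5.29 ± 0.26) and the prostaglandin-degrading enzyme gene Hpgd (-5.01 ± 0.17). Next came Cd209f (-4.74 ± 0.46), Retnla (-4.71 ± 0.38) and Pla2g2d (-4.64 ± 0.30). In all, 1145 genes were called, 573 higher and 572 lower.

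By gene group, 15 of 17 tested glycolysis and hypoxia genes rose at day 1.5 (15 also when adjusted over the list alone, median log2 fold change 1.77, camera adjusted p = 6.08e-16). They included Vegfa, a blood vessel growth factor (3.69 ± 0.20), the oxygen sensor Egln3 (3.61 ± 0.23), Mif (2.47 ± 0.13) and the glycolytic enzyme Pgam1 (2.38 ± 0.11). Among oxidative phosphorylation genes 5 of 23 rose (5 adjusted over the list alone, 1.53e-09), led by Cox5a (1.33 ± 0.12) and Ndufv1 (1.29 ± 0.17). Monocyte markers rose in 9 of 12 (9 adjusted over the list alone, median 1.43, 2.14e-09). Type I interferon response genes rose in 7 of 15 (7 over the list alone, 5.20e-07). Irf7, a transcription factor of that response, stood at 2.81 ± 0.18 and Ifit2 at 1.95 ± 0.26. Of the lipid-handling genes of phagocytes 11 of 20 rose and 1 fell (11 and 1 over the list alone, 5.06e-06), including the fatty acid binding protein gene Fabp5 (4.63 ± 0.16) and the galectin gene Lgals3 (3.04 ± 0.17). Of the neutrophil markers 3 of 6 rose (3 over the list alone, 0.00298): S100a8 (5.10 ± 0.33), Mmp8 (4.38 ± 0.33) and S100a9 (2.31 ± 0.18), while Csf3r stood at 0.76 ± 0.19.

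Barrier and perivascular macrophage markers, genes of macrophages that line vessels and tissue borders, fell in 11 of 17 at day 1.5 (11 over the list alone, median -2.41, camera adjusted p = 4.23e-13). The lectin gene Cd209d stood at -3.63 ± 0.42 and Timd4, a receptor for dying cells, at -3.44 ± 0.21. Cholesterol synthesis genes fell in 6 of 15 (6 over the list alone, 7.76e-05), among them Idi1 (-1.71 ± 0.24) and Hmgcs1 (-1.63 ± 0.15). Microglia markers fell in 7 and rose in 2 of 12 (7 and 2 over the list alone, 0.00309, and adjusted p = 0.234 with an estimated correlation). Sparc stood at -3.88 ± 0.45, Gpr34 at -3.56 ± 0.23 and Siglech at -3.19 ± 0.30. Schwann cell and myelin genes, a list named after the glia that wrap axons, fell in 6 of 11 (6 over the list alone, 6.83e-05, adjusted p = 0.141 with an estimated correlation). Pmp22 stood at -3.09 ± 0.14, S100b at -2.23 ± 0.48 and Mbp at -1.88 ± 0.20, and the 6 included Egr2, which is also in the list of immediate early genes. Immediate early and heat shock genes, which tissue dissociation can induce, fell in 6 of 13 (6 over the list alone, 1.41e-06, adjusted p = 0.223 with an estimated correlation), among them Hspa1a (-2.12 ± 0.27) and Jun (-1.71 ± 0.13). Matrix and remodelling genes rose in 7 and fell in 2 of 12 (7 and 2 over the list alone, 0.00375, adjusted p = 0.126 with an estimated correlation). The fibronectin gene Fn1 stood at 5.09 ± 0.41. Of the cell cycle genes 3 of 24 fell (3 over the list alone, 4.57e-04, adjusted p = 0.277 with an estimated correlation), namely Top2a (-1.31 ± 0.25), Birc5 (-1.26 ± 0.18) and Ccnb2 (-1.01 ± 0.27). Each of the 4 sort genes fell, from H2-Eb1 (-3.28 ± 0.14) to Cd74 (-2.24 ± 0.14), in means that weigh the sorted groups equally.

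At day 5 the same question was asked of the MHCII high and MHCII low groups together. Gpnmb rose by 5.99 ± 0.27 (SE, 6 arrays against 3), Saa3 by 5.12 ± 0.32, Fn1 by 4.57 ± 0.41, the chemokine gene Ccl8 by 4.22 ± 0.28 and Fabp5 by 4.13 ± 0.16. Thbs1 (4.13 ± 0.26), Arg1 (3.78 ± 0.18) and the lectin receptor gene Clec4d (3.62 ± 0.22) were also higher. Adjusted p values of these 8 rises ran from 1.37e-13 to 2.75e-08. Gpr165 (-5.15 ± 0.22), Tcim (-4.24 ± 0.29), P3h2 (-3.99 ± 0.26), Pla2g2d (-3.89 ± 0.30) and Hs3st3a1 (-3.88 ± 0.24) fell most. Lilra5 (-3.83 ± 0.30), the peptide transporter gene Slc15a2 (-3.62 ± 0.19) and the imprinted gene Peg10 (-3.39 ± 0.22) followed. Limma called 740 genes, 472 higher and 268 lower. The fit took the 6 arrays as independent although their numbers were taken to pair them, so these errors and p-values may be too small.

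Cell cycle genes rose in 13 of 24 at day 5 (13 over the list alone, camera adjusted p = 2.84e-06, adjusted p = 0.137 with an estimated correlation), among them the cyclins Ccnb2 (1.73 ± 0.27) and Ccna2 (1.73 ± 0.21), Bub1 (1.66 ± 0.31) and Birc5 (1.53 ± 0.18). Lipid-handling genes rose in 10 and fell in 1 of 20 (11 and 1 when adjusted over the list alone, 2.14e-09). The cholesterol exporter gene Abcg1 stood at 3.06 ± 0.20 and Lgals3 at 2.43 ± 0.17. Cholesterol synthesis genes fell in 9 of 15 (9 over the list alone, 2.57e-09), led by Idi1 (-2.26 ± 0.24) and Sqle (-2.15 ± 0.15). Monocyte markers rose in 6 of 12 (6 over the list alone, 5.49e-04). Plac8 stood at 3.56 ± 0.29 and Hp at 3.54 ± 0.25. Interferon response genes rose in 8 and fell in 1 of 15 (8 and 1 over the list alone, 6.78e-06). Ifit2 stood at 2.42 ± 0.26, Irf7 at 2.07 ± 0.18 and the chemokine gene Cxcl10, which fell, at -1.24 ± 0.30. Matrix genes rose in 7 and fell in 1 of 12 (7 and 1 over the list alone, 0.00346, adjusted p = 0.124 with an estimated correlation). The protease gene Mmp14 stood at 3.44 ± 0.36. Barrier markers fell in 4 of 17 (4 over the list alone, 5.68e-05, adjusted p = 0.137 with an estimated correlation), and Cd209a (-2.54 ± 0.32) and Timd4 (-2.48 ± 0.21) fell most. Of the Schwann cell and myelin genes 5 of 11 fell (5 over the list alone, 5.57e-04, adjusted p = 0.207 with an estimated correlation), among them Pllp (-1.48 ± 0.20) and Mbp (-1.42 ± 0.20).

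Day 10 was compared with steady state in the same way, with 7 arrays against 3. Gpnmb (5.18 ± 0.27), Ccl8 (5.01 ± 0.27), the heparan sulfate cleaving enzyme gene Hpse (3.72 ± 0.23) and Cd200r4 (3.31 ± 0.19) rose most. Clec4d rose by 3.25 ± 0.21, Fabp5 by 3.16 ± 0.16, the glutathione transferase gene Mgst1 by 3.11 ± 0.14 and the aminopeptidase gene Enpep by 2.97 ± 0.22. Their adjusted p values ran from 1.66e-12 to 1.92e-09. Gpr165 fell by 4.51 ± 0.22, and Hs3st3a1 (-3.46 ± 0.23), Lilra5 (-3.36 ± 0.30), Peg10 (-3.11 ± 0.22), Tcim (-3.01 ± 0.28), Drp2 (-2.91 ± 0.22), Tnfsf9 (-2.70 ± 0.35) and Sgce (-2.59 ± 0.20) fell as well. There were 405 calls, 253 higher and 152 lower.

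Lipid-handling genes rose in 10 of 20 at day 10 (10 over the list alone, median 1.04, camera adjusted p = 1.06e-12). Abcg1 stood at 2.13 ± 0.20 and Lgals3 at 1.91 ± 0.16. Interferon response genes rose in 9 and fell in 1 of 15 (9 and 1 over the list alone, 1.42e-12). Ifit2 stood at 2.79 ± 0.25, Irf7 at 2.35 ± 0.18 and Ifit1 at 1.78 ± 0.18. Cholesterol synthesis genes fell in 5 of 15 (5 over the list alone, 1.03e-10), among them Idi1 (-1.97 ± 0.24) and Cyp51 (-1.66 ± 0.14). Of the inflammatory cytokine and chemokine genes 8 of 18 fell and 1 rose (8 and 1 over the list alone, 8.25e-08, adjusted p = 0.126 with an estimated correlation). Il1a stood at -2.21 ± 0.44, Il6 at -1.91 ± 0.50 and Ccl5, which rose, at 1.46 ± 0.30. Immediate early and heat shock genes, 2 of 13 of which fell at the same time (2 over the list alone, 9.96e-07, adjusted p = 0.214 with an estimated correlation), included Hspa1a (-1.27 ± 0.27) and Egr2 (-1.07 ± 0.17). Among Schwann cell and myelin genes 5 of 11 fell (5 over the list alone, 3.19e-05, adjusted p = 0.127 with an estimated correlation). S100b stood at -1.85 ± 0.47 and Mbp at -1.54 ± 0.20.

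By day 37 the question was whether macrophages of the injured nerve still differed from those of uninjured nerve. Ccl8 was 4.85 ± 0.32 higher on the log2 scale (SE, 3 arrays against 3), Enpep 3.98 ± 0.26, Hpse 3.38 ± 0.27 and the ribonuclease gene Rnase2a 3.37 ± 0.60. Mgst1 (3.27 ± 0.16), Plac8 (3.23 ± 0.33), Gpnmb (3.13 ± 0.31) and the matrix protein gene Dpt (3.05 ± 0.46) were higher as well, with adjusted p values from 1.88e-11 to 7.21e-04. Beside Dpt, a gene of the fibroblast list, the collagen genes of that list showed 0.01 ± 0.15 (Col1a1) and 0.23 ± 0.15 (Col3a1). Gpr165 (-4.07 ± 0.26), Hs3st3a1 (-2.93 ± 0.27), Peg10 (-2.60 ± 0.26), Drp2 (-2.45 ± 0.27) and Sgce (-2.40 ± 0.23) fell most. Glcci1 (-2.11 ± 0.27), Idi1 (-2.11 ± 0.28) and Lilra5 (-2.09 ± 0.35) were also lower. Limma called 256 genes, 185 higher and 71 lower. Interferon response genes rose in 9 of 15 (9 over the list alone, median 1.34, camera adjusted p = 2.18e-16). Ifit2 stood at 1.82 ± 0.30 and Ifit1 at 1.63 ± 0.21. Lipid-handling genes rose in 4 of 20 (4 over the list alone, 3.54e-08) and monocyte markers in 1 of 12 (Plac8; 1 over the list alone, 0.00658). Cholesterol synthesis genes fell in 4 of 15 (4 over the list alone, 6.06e-13). Barrier markers rose in 5 of 17 (5 over the list alone, 1.02e-04, adjusted p = 0.154 with an estimated correlation). Cd209d stood at 2.60 ± 0.48, Cd209f at 2.31 ± 0.54 and the ficolin gene Fcna at 1.93 ± 0.24. Schwann cell and myelin genes fell in 3 of 11 (4 over the list alone, 0.00286, adjusted p = 0.277 with an estimated correlation): Pllp (-1.40 ± 0.23), Mbp (-1.21 ± 0.23) and Mal (-1.03 ± 0.30). The count was 107 (80 higher and 27 lower) when the 6 arrays were fitted alone, and 481 (362 and 119) without steady state replicate 2 and day 37 replicate 1, a pair chosen after seeing the data.

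**Figure D2:**
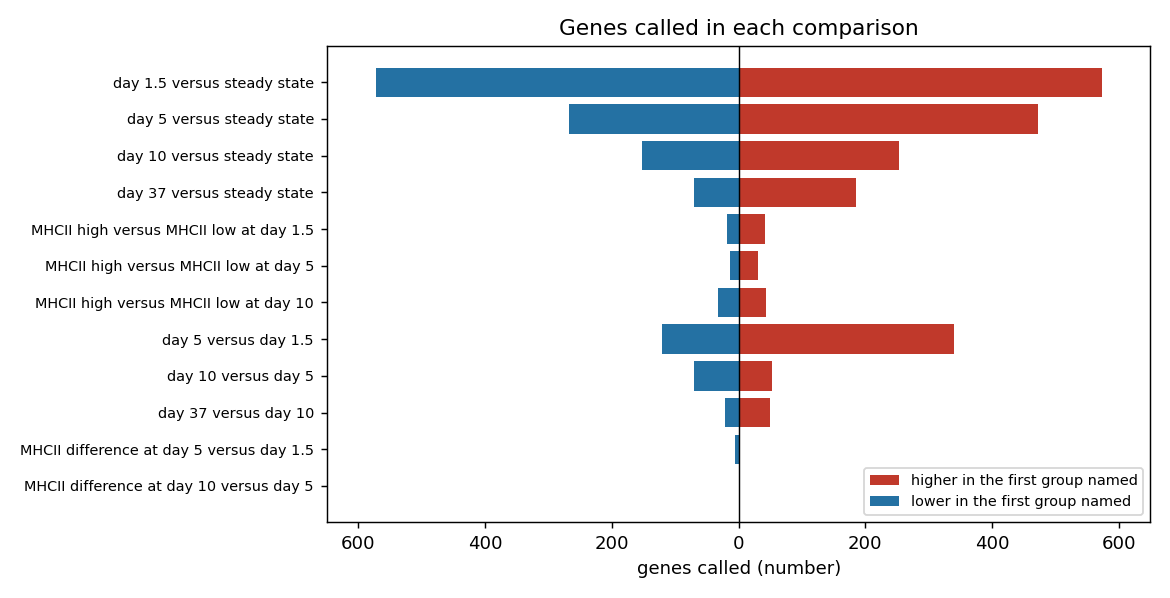
Number of genes called (x axis) in each of the 12 comparisons (y axis), with genes higher in the group or difference named first to the right in red and those lower to the left in blue. Calls against steady state fall from 1145 at day 1.5 to 256 at day 37, and the comparisons of the MHCII difference between days hold 7 and 0.

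MHCII high and MHCII low macrophages were compared within each day, to find what else differs between cells sorted by this molecule. At day 1.5 the high group had more Retnla (3.77 ± 0.44, SE, 3 arrays against 3), a secreted product of alternatively activated macrophages, and more of the lectin genes Clec4b1 (3.30 ± 0.25) and Cd209a (2.73 ± 0.36). Klrd1 was higher by 2.74 ± 0.47. Il1r2, the decoy receptor for interleukin 1, was higher by 2.68 ± 0.14 and Tmem176a by 2.38 ± 0.23, with adjusted p values of the 6 genes from 1.15e-11 to 0.00236. S100a8 (-1.79 ± 0.38), Bhlhe41 (-1.62 ± 0.34), Mmp8 (-1.55 ± 0.38), the scavenger chemokine receptor gene Ackr3 (-1.47 ± 0.18), the chemokine gene Cxcl3 (-1.45 ± 0.23) and Flrt2 (-1.39 ± 0.28) were lower. The sort genes included, 60 genes were called, 41 higher and 19 lower. Antigen presentation genes beyond the sort genes were higher in 2 of 11 (2 over the list alone, camera adjusted p = 5.21e-07), namely Ciita, the master regulator of MHC class II transcription (1.33 ± 0.25), and H2-DMa (1.20 ± 0.13). Dendritic cell markers were higher in 2 of 9 (2 over the list alone, 3.48e-08), Dpp4 (2.04 ± 0.26) and Kmo (1.62 ± 0.23). Cholesterol synthesis genes were higher in 3 of 15 (3 over the list alone, 2.51e-09). Idi1 stood at 1.49 ± 0.28. Glycolysis and hypoxia genes were lower in 1 of 17 (Egln3, -1.20 ± 0.26; 1 over the list alone), with a list median of -0.39 (3.46e-13). Lipid-handling genes gave 0 calls of 20 over all genes by limma (11 at an unadjusted p under 0.05) and 1 adjusted over the list alone, but their median was -0.38 (2.58e-14), and Gpnmb stood at -1.24 ± 0.31 (adjusted p = 0.065). Neutrophil markers were lower in 2 of 6 (2 over the list alone, 4.27e-04). Among their uncalled members Mmp9 stood at -0.75 (limma adjusted p = 0.181) and Retnlg at 0.75 (0.648), so the list did not go 1 way. The list written as monocyte markers had 1 of 12 higher (Cd177, 1.11 ± 0.16, 1 over the list alone, 5.77e-06). Without day 1.5 MHCII high replicate 2 the count was 37 (30 higher and 7 lower). It was 53 (42 and 11) without high replicate 3 and 42 (36 and 6) without low replicate 1.

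At day 5 Clec4b1 (2.45 ± 0.25), Klrb1b (2.37 ± 0.49), Tnip3, an inhibitor of NF-kB signalling (2.35 ± 0.28), and Ciita (2.33 ± 0.25) were higher in the MHCII high group, as were Cd226 (2.14 ± 0.38) and Dpp4 (1.67 ± 0.26). Vsig4, a complement receptor of resident macrophages (-2.50 ± 0.34), the iron exporter ferroportin, Slc40a1 (-1.94 ± 0.31), Tcim (-1.80 ± 0.33), Pdpn (-1.60 ± 0.26), Mmp27 (-1.45 ± 0.23) and Ctla2a (-1.43 ± 0.28) were lower. There were 43 calls, 30 higher and 13 lower, with adjusted p values of the named genes from 2.72e-06 to 0.0199. Cell cycle genes gave 0 calls of 24 by limma (0 over the list alone, 13 at an unadjusted p under 0.05), yet shifted up as a list (median 0.55, camera adjusted p = 9.83e-17). Antigen presentation genes were higher in 2 of 11 (2 over the list alone, 3.56e-05) and dendritic cell markers in 1 of 9 (Dpp4; 1 over the list alone, 6.11e-06, but adjusted p = 0.181 with an estimated correlation and the replicate block). Monocyte markers shifted up with 0 of 12 called by limma (0 over the list alone, 4 at an unadjusted p under 0.05, median 0.28, 4.57e-04, but adjusted p = 0.134 with an estimated correlation and the block). Iron and haem genes were lower in 1 of 10 (Slc40a1; 1 over the list alone, 1.30e-06). Lipid-handling genes shifted down with 0 of 20 called by limma (0 over the list alone, 6 at an unadjusted p under 0.05, median -0.20, 2.79e-05, but adjusted p = 0.0807 with an estimated correlation and the block). Leaving out day 5 MHCII low replicate 3 gave a count of 28 (22 higher and 6 lower), and the lower calls were 6 without high replicate 3, 8 without low replicate 1 or 2 and 6 without the arrays that held Y-linked transcripts. A replicate block within each day gave 48 calls (30 higher and 18 lower), of which 36 were shared. With it Klrb1b was not called (2.37 ± 0.47, adjusted p = 0.0568). The block also gave shifts up of immediate early and heat shock genes (0 calls, camera adjusted p = 0.0138, against 0.0513 without it) and Schwann cell and myelin genes (0 calls, 0.0389 against 0.114), and down of barrier markers (0 calls, 0.04 against 0.123), all lost with an estimated correlation (adjusted p = 0.55, 0.55 and 0.425).

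At day 10 Rnase2a (2.40 ± 0.56, SE, 4 arrays against 3), Slamf8 (2.24 ± 0.28), Ciita (2.21 ± 0.23), Tnip3 (2.12 ± 0.26), the lysozyme gene Lyz1 (1.88 ± 0.33) and Plbd1 (1.79 ± 0.11) were higher in MHCII high macrophages. Vsig4 (-3.02 ± 0.32), Gpnmb (-2.65 ± 0.29), Slc40a1 (-2.01 ± 0.29), the scavenger receptor gene Colec12 (-1.98 ± 0.28), Tcim (-1.82 ± 0.31) and Mmp27 (-1.70 ± 0.22) were lower. Adjusted p values of the 12 genes ran from 7.39e-10 to 0.0302. Limma called 75 genes, 43 higher and 32 lower. Without day 10 MHCII low replicate 3 it called 42 higher and 54 lower and with array weights 41 and 46, so that lower calls were then the more numerous. Without low replicate 1 it called 32 and 21, and without the arrays that held Y-linked transcripts 33 and 17. Lipid-handling genes were lower in 3 of 20 (4 over the list alone, camera adjusted p = 1.97e-08): Gpnmb, Fabp5 (-1.58 ± 0.18) and Syngr1 (-1.52 ± 0.12). Cell cycle genes were higher in 2 of 24 (2 over the list alone, 3.64e-13), Rrm2 (1.22 ± 0.24) and Top2a (1.09 ± 0.27). Antigen presentation genes were higher in 2 of 11 (2 over the list alone, 6.78e-06) and dendritic cell markers in 2 of 9 (4 over the list alone, 2.87e-07), with Naaa at 1.14 ± 0.14. Monocyte markers were higher in 1 of 12 (2 over the list alone, 1.04e-04), namely Ccr2, the receptor that draws monocytes from blood (1.58 ± 0.13).

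Whether the MHCII difference itself changed between days was tested as a difference between differences. From day 1.5 to day 5 the high minus low difference changed by -2.38 ± 0.20 (SE) for Il1r2 (adjusted p = 6.28e-07), -1.97 ± 0.27 for Hpgd (0.00159) and -1.79 ± 0.32 for Tmem176a (0.0425). It changed by -2.03 ± 0.38 for the sort gene H2-Aa (0.0425), while that of Tnip3 rose by 2.07 ± 0.40 (0.0461). Limma called 7 genes, 2 higher and 5 lower. It called 3 when quantile normalization was repeated (0 higher and 3 lower), 4 with no filter, 3 when the 12 arrays were fitted alone, 26 with array weights and 2 without the arrays that held Y-linked transcripts. With a replicate block within each day it called 5 (1 higher and 4 lower, 4 of them shared), without Tnip3 (adjusted p = 0.116) and H2-Aa (0.165). It called 3, with 0 higher, without day 1.5 MHCII high replicate 1 or 2 or any 1 of the 6 day 5 arrays, and 5 to 7, with 0 or 1 higher, without any other day 1.5 array. The sort genes moved as a list, with 1 of 4 lower (1 over the list alone, median -0.87, camera adjusted p = 1.18e-11). With 0 calls by limma among 15 and 17 genes the cholesterol synthesis list shifted down (1 lower over the list alone, 5 at an unadjusted p under 0.05, 7.28e-07) and the glycolysis and hypoxia list up (0 over the list alone, 2 unadjusted, 1.02e-06). From day 5 to day 10 limma called 0 genes, with 354 at an unadjusted p under 0.05, and 1 with array weights or with a trended, robust variance, and 2 without day 10 MHCII high replicate 1. The sort genes again moved as a list (0 calls of 4, 1 lower over the list alone, 4 at an unadjusted p under 0.05, median -0.66, 1.53e-09).

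Successive days were compared directly, which avoids the shared steady-state arrays. From day 1.5 to day 5 Cd209f rose by 4.29 ± 0.38 (SE, 6 arrays against 6), Retnla by 4.12 ± 0.31, Rasgrp3 by 3.48 ± 0.22, Fcna by 3.25 ± 0.17 and Chp2 by 3.19 ± 0.16. Vcan (-4.18 ± 0.14), the platelet and myeloid chemokine gene Ppbp (-4.09 ± 0.24), Chil3 (-4.04 ± 0.37), the leukotriene receptor gene Ltb4r1 (-3.44 ± 0.17) and Cxcl3 (-3.37 ± 0.17) fell. Adjusted p values of the 10 genes ran from 4.47e-15 to 2.39e-08. There were 461 calls, 340 higher and 121 lower. Cell cycle genes rose in 14 of 24 (14 over the list alone, camera adjusted p = 7.99e-20), with Birc5 at 2.79 ± 0.15. Barrier markers rose in 9 of 17 (9 over the list alone, 1.61e-10). Lyve1, a hyaluronan receptor, stood at 2.44 ± 0.18. Glycolysis and hypoxia genes fell in 10 of 17 (10 over the list alone, 7.01e-25). Egln3 stood at -3.16 ± 0.18 and Vegfa at -2.53 ± 0.16. Monocyte markers fell in 6 of 12 (6 over the list alone, 5.09e-12) and neutrophil markers in 3 of 6 (3 over the list alone, 0.0023). S100a8 stood at -2.30 ± 0.27.

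From day 5 to day 10 Cd209d (2.50 ± 0.33, SE, 7 arrays against 6), Pla2g2d (2.41 ± 0.24), Enpep (2.34 ± 0.17), Cd209b (2.31 ± 0.25) and Dpt (2.09 ± 0.32) rose. Saa3 (-3.99 ± 0.26), Arg1 (-2.76 ± 0.14), Fn1 (-2.70 ± 0.33), S100a8 (-2.49 ± 0.26) and Hp (-2.46 ± 0.20) fell. Limma called 123 genes, 52 higher and 71 lower, and the adjusted p values of the 10 genes ran from 3.35e-11 to 1.51e-04. Barrier markers rose in 6 of 17 (6 over the list alone, camera adjusted p = 3.95e-18). Cell cycle genes fell in 8 of 24 (8 over the list alone, 3.17e-18). Ccnb2 stood at -1.50 ± 0.21. Matrix genes fell in 3 of 12 (3 over the list alone, 1.14e-05) and monocyte markers in 3 of 12 (3 over the list alone, 2.44e-05). Without the arrays that held Y-linked transcripts limma called 182 genes (79 higher and 103 lower). With 0 calls each, by limma and over the list alone, interferon response genes shifted up (median 0.34, 5.06e-06; 7 of 15 at an unadjusted p under 0.05) and glycolysis and hypoxia genes down (-0.32, 1.70e-05; 10 of 17). From day 10 to day 37 Tnfsf9 (2.67 ± 0.35, SE, 3 arrays against 7), Il6 (2.55 ± 0.50), the metallothionein gene Mt2 (2.26 ± 0.25), Cxcl12 (1.98 ± 0.19) and Hbegf (1.86 ± 0.30) rose. Nrep (-1.78 ± 0.32), Thbs1 (-1.63 ± 0.26), Fcrl1 (-1.56 ± 0.30), Clec4n (-1.50 ± 0.16) and Tmem86a (-1.25 ± 0.12) fell, with adjusted p values of the 10 genes from 3.19e-06 to 0.00547. Inflammatory cytokine and chemokine genes, with 1 of 18 higher (2 over the list alone, camera adjusted p = 5.44e-10, adjusted p = 0.072 with an estimated correlation), moved up as a list. Beside them stood immediate early and heat shock genes, with 1 of 13 higher (1 over the list alone, 5.40e-09, adjusted p = 0.133 with an estimated correlation). Lipid-handling genes fell in 2 of 20 (2 over the list alone, 9.00e-11), Gpnmb (-2.05 ± 0.27) and Fabp5 (-1.33 ± 0.16). Both genes were lower in MHCII high than in MHCII low macrophages at day 10, where the subsets weighed equally, while day 37 was unsplit. A different mix of the subsets can therefore not be told apart from a change over time in this comparison. The 72 calls (50 higher and 22 lower) became 111 (62 and 49) without day 10 MHCII low replicate 3, 49 (28 and 21) without day 37 replicate 2, 59 (31 and 28) without day 37 replicate 3 and 125 (87 and 38) with array weights. They numbered 44 (19 higher and 25 lower) without the 7 arrays that held Y-linked transcripts and had 78 higher and 23 lower without steady state replicate 2 and day 37 replicate 1, sets chosen after seeing the data.

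**Figure D3:**
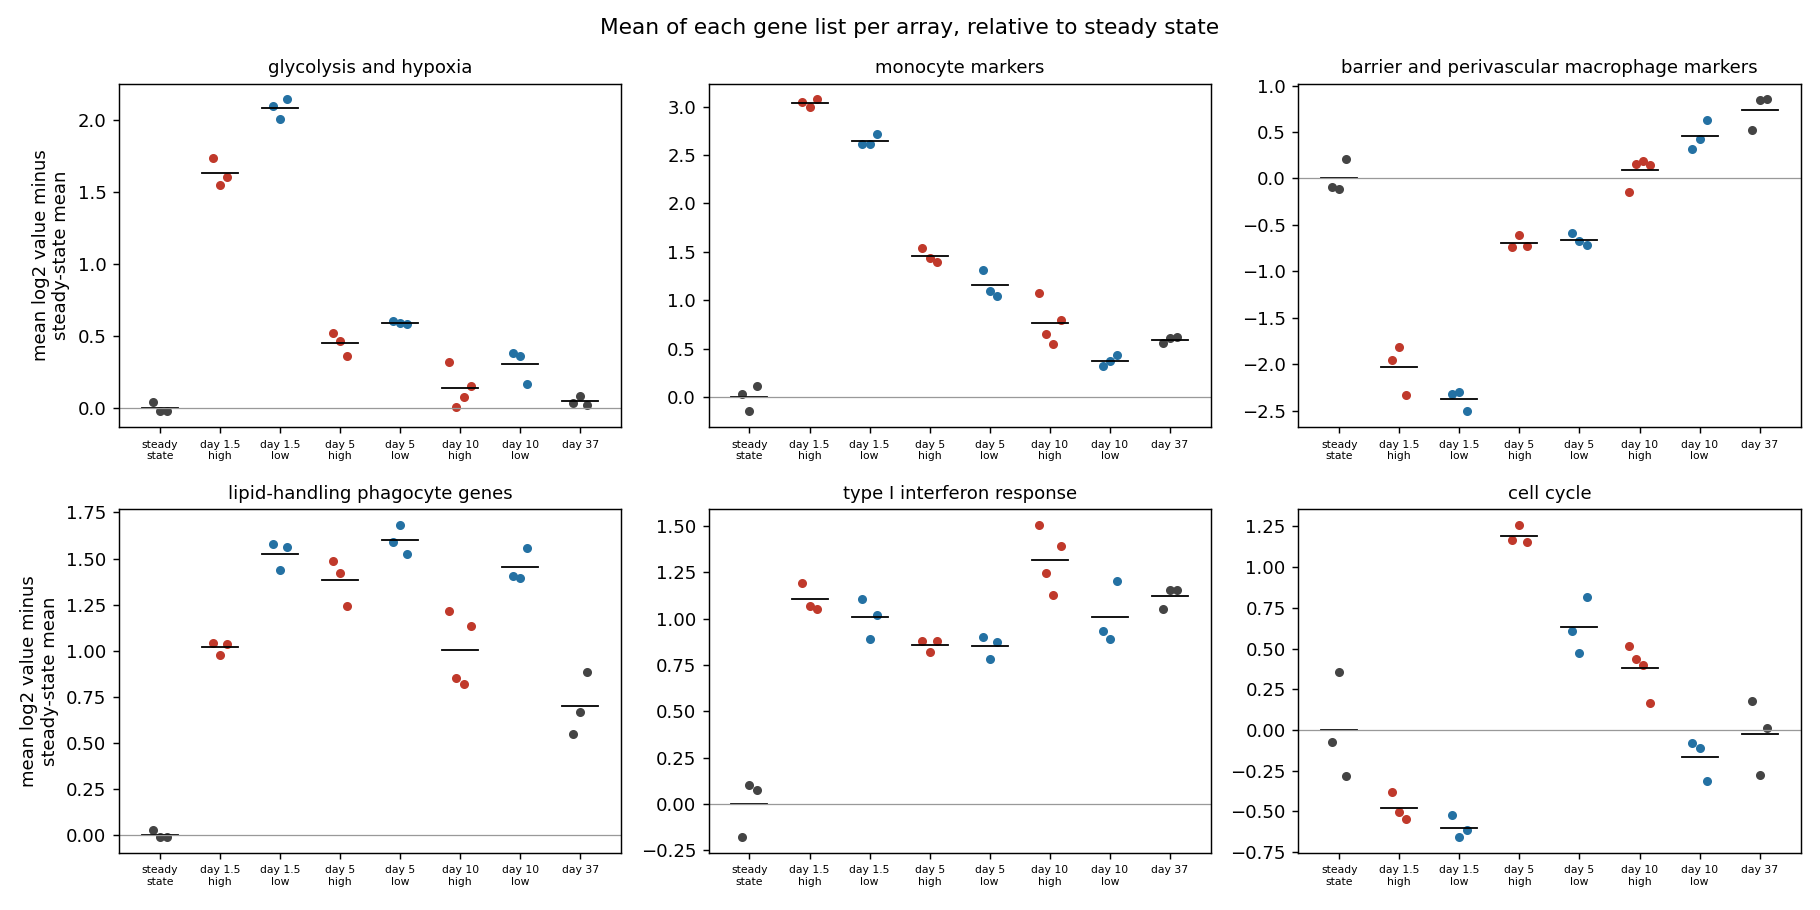
Mean log2 value of the tested members of 6 gene lists in each array, minus the steady-state mean (y axis), in the 8 groups (x axis); each point is an array and each bar the group mean, with MHCII high in red, MHCII low in blue and unsplit groups in grey. Glycolysis and hypoxia genes and monocyte markers are highest at day 1.5, cell cycle genes at day 5, and all arrays after crush lie above the steady-state arrays for the interferon response.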

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

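The tests of the 3 patterns weighed here, the permutation of residuals, and the splits that respect the pairs of day 5, were chosen after the results were seen; the other splits of the samples were planned.

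S100a8, S100a9 and Mmp8, genes abundant in neutrophils, were higher at day 1.5 by 5.10 ± 0.33, 2.31 ± 0.18 and 4.38 ± 0.33 (log2, SE). RNA from neutrophils among the sorted cells stays open: the median log2 fold change of all 12 neutrophil markers, tested with no filter, was 0.41 (-0.06 to 2.31). The bounds of this median and of that of the monocyte markers run over genes as if independent, and not over arrays. Of the others Csf3r rose by 0.755 (adjusted p = 0.0049) and Lcn2 by 0.54 (0.0124), Mmp9 fell by 0.63 and Retnlg stood at 0.70 (0.0963). Cxcr2, Ngp, Camp, Ltf and Ly6g, at log2 3.92 to 5.56 in steady state, stood at 0.28, 0.01, 0.11, -0.12 and -0.06. S100a8, S100a9 and Mmp8 rose from a like level (4.94, 5.03 and 4.35). A low start alone thus does not hide a large rise, though a small one may be compressed. More cells of monocyte kind at this time after injury also stays open as a hypothesis: the median of the monocyte markers was 1.43, with a lower bound of 0.98 where 1 was needed. The labels call the samples macrophages, and the gates of the sort are not given in them.

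Myelin genes were lower at day 1.5, among them Mbp (-1.88 ± 0.20), S100b (-2.23 ± 0.48), Pllp (-1.61 ± 0.20), Mal (-1.41 ± 0.26) and Pmp22 (-3.09 ± 0.14). Mbp, S100b, Pllp and Mal, the called genes other than Pmp22 and Egr2, varied together within groups, with a mean correlation of 0.710 (0.605 without steady state) at the 100th percentile of random sets of genes of like level, so less RNA from Schwann cells among the sorted cells is a candidate explanation for these 4. The 5 members of the list that were not called stood at -0.07 (Sox10), -0.17 (Cnp), -0.25 (Ngfr), -0.32 (Mag) and -0.35 (Ncmap), and at day 37 at -0.16, 0.38, -0.06, -0.42 and 0.31; they lay at log2 6.08 to 6.80 in steady state but for Cnp (8.36), so they weigh against that source without excluding it. For Pmp22 that source stays open: at day 37 its log2 fold change lay 1.13 above the median of the 5 other called myelin genes, Egr2 included, but the bounds (-0.06 to 2.33) hold 0. No biological explanation was tested for these genes, and a change within macrophages stays open.

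At day 37, 256 genes still differed from steady state. Of these, 236 were kept with Y-linked transcripts as a covariate (median ratio of folds 0.987) and 221 without steady state replicate 2 (0.991). Among these 6 arrays only that replicate held Y-linked transcripts, so both fits probe the same array. They argue against that array, with the sex-linked difference it carries, as the cause. The median of immediate early and heat shock genes was -0.0521 (-0.23 to 0.08). Its bounds run over the 13 genes as if these were independent, and not over arrays. With an estimated correlation of 0.62 between the genes, the bounds are too narrow to decide on a different response to tissue dissociation. Time after injury may account for the calls, as a hypothesis found and tested on the same data. Other differences between the groups, such as a batch that the labels do not name, were not tested. The 10 splits of these 6 arrays are too few for a share under 0.05, with 107 genes in the real split (1 of 10) and 0 at most in the others. Days 10 and 37 share 3 control arrays. At both, 137 genes were called higher and 55 lower (0.01 and 0 in simulations with shared controls and no effect). Across genes, which are not independent replicates, the correlation was 0.797, against 0.591 in the simulations. A correlation cannot be split into parts, so the covariance was compared too: 0.139 was observed and 0.0226 simulated, a difference of 0.116. The simulations gave all groups the same spread of each gene. The steady-state arrays had the lowest correlations within their group (0.942 to 0.948), so the simulated values may be too low. Part of the likeness of these days may thus come from the shared controls, and how large a part was not settled.

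Chance was tested by splitting the arrays of each comparison otherwise, fitted alone in 2 groups. In comparisons of days this pools the MHCII high and low arrays of a day, so the counts tested differ from those reported above (for day 37 against 10, 30 and not 72). These splits take the arrays of days 1.5 and 10 as independent, which was not established and which the values in part speak against. At day 1.5 each MHCII low array was closest to the high array of its own number (3 of 3). At day 10 high replicate 4 and low replicate 3 correlated at 0.34. Splits that keep such pairs of these days together were not run. Only if these arrays are independent is chance excluded for the counts that follow in this paragraph. The real split called 1130 genes at day 1.5 (highest other 7, 1 of 84 splits as large), 355 at day 10 (31, 1 of 100), 54 for MHCII high against low at day 10 (3, 1 of 35), 456 for day 5 against 1.5 (0, 1 of 100) and 117 for day 10 against 5 (0, 1 of 100). Among splits that keep the same-numbered arrays of day 5 together, 1 of 46 and 1 of 100 were as large in the last 2 (highest others 0 and 112, the latter with only 1 day 10 array out of place). For day 37 against 10 it called 30 and 2 of 100 splits gave as many; the highest other, with 52, set the 3 day 10 MHCII low arrays against the rest and so follows the sort.

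For 3 further counts chance was not excluded by these splits even under that condition. At day 5 against steady state the real split called 713 genes (highest other 13, 1 of 84), but only 10 splits keep the pairs of day 5 together, too few for a share under 0.05 (highest other 3, 1 of 10). For MHCII high against low at days 1.5 and 5 the 10 splits are too few, with 64 and 43 genes in the real split (1 and 1 of 10) and 0 and 1 at most in the others; at day 5, 4 splits part every pair (1 of 4, highest other 0).

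For the MHCII difference from day 1.5 to day 5 the planned permutation of labels within each day did not exclude chance: 10 of 100 permutations gave as many as the real 3 genes (highest other 8). Permuted labels carry the real MHCII difference into the permutations; with residuals permuted instead, a version added after that result was seen, 1 of 100 gave as many as 3 (the real one, highest other 1). From day 5 to day 10 neither version can test chance, since the real count by limma was 0 and any permutation (100 and 100 of 100) gives as many; the highest others were 116 with labels, where the MHCII difference itself is carried over, and 7 with residuals. As the versions differ, chance is left open for the count of 3, which comes from the 12 arrays fitted alone and shares 2 genes with the 7 called by limma over all arrays; for the 7 as a count it was not tested. The MHCII difference of these 7 changed from day 1.5 to day 5 by 1.68 for Car6 (adjusted p = 0.045), -2.03 for H2-Aa (0.0425), -1.97 for Hpgd (0.00159), -2.38 for Il1r2 (6.28e-07), -1.79 for Tmem176a (0.0425), -1.43 for Tmem176b (0.00159) and 2.07 for Tnip3 (0.0461). Of the gene lists, the medians of that change were -0.87 for the sort genes, -0.27 for cholesterol synthesis and 0.38 for glycolysis and hypoxia, and -0.66 for the sort genes from day 5 to day 10.

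In the group of 4, day 10 MHCII high, 21 of 183 tested values lay far from the others by Dixon's test, where chance gives about 1 in 20 (9.15); 12 were in replicate 1, 3 in replicate 2, 2 in replicate 3 and 4 in replicate 4. Replicate 1 was higher than the other 3 for Hbegf (8.42, others 6.98 to 7.20), Thbs1 (9.11, 7.96 to 8.14), S100a8 (5.75, 4.64 to 4.81), Egr2 (12.69, 12.03 to 12.07), Atf3 (12.72, 11.82 to 11.93), Cxcl10 (10.46, 8.57 to 8.85) and Ptgs2 (10.35, 8.83 to 8.88), and for the mean of inflammatory cytokines and chemokines (10.12, 9.22 to 9.37). It was lower for Slc40a1 (6.38, 7.33 to 7.51), Cxcl12 (6.63, 7.25 to 7.35), Clec4n (9.24, 9.79 to 9.83) and the mean of barrier markers (10.56, 10.85 to 10.90). Replicate 2 stood apart for H2-Eb1 (12.77, 12.87 to 12.89), C1qb (12.78, 12.72 to 12.73) and C1qa (13.14, 13 to 13.02), and replicate 3 for Pgam1 (9.19, 9.32 to 9.34) and Naaa (10.64, 10.46 to 10.49). Replicate 4 was lower for Plbd1 (11.03, 11.43 to 11.47), Olfml3 (8.49, 9.79 to 9.96), the mean of core macrophage genes (11.38, 11.48 to 11.49) and that of microglia markers (8.91, 9.28 to 9.33). Among 7121 tested probe sets without exactly 1 gene symbol, 504 were called at day 1.5, 280 higher and 224 lower.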

How the results depend on the processing

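The Y-linked covariate, the fit without the 7 arrays that held Y-linked transcripts, and the fit without steady state replicate 2 and day 37 replicate 1 were chosen after seeing the data; all others were planned. The 47-array table held the same values for these arrays, so its counts had to be equal and say nothing on stability. Counts of called genes stayed within 1.5 times their value with a floor of log2 7, the mean of probe sets and the Y-linked covariate. With no minimum fold they were 4461, 3920, 2430 and 1100 at days 1.5, 5, 10 and 37 against steady state, 115, 75 and 154 for MHCII high against low at days 1.5, 5 and 10, and 2988, 1234 and 292 for day 5 against 1.5, 10 against 5 and 37 against 10, since that choice only drops a condition. With only the groups compared day 37 against steady state gave 107 and the MHCII difference from day 1.5 to 5 gave 3. Array weights gave 125 for day 37 against 10, and 26 and 1 for the MHCII difference from day 1.5 to 5 and from day 5 to 10. That first difference gave 3 with quantile normalization repeated (0 higher, 3 lower), 4 with no filter and 3 at an adjusted p under 0.01, and the second gave 1 with a trended, robust variance. Without the 7 arrays day 37 against 10 gave 44 and the MHCII differences 2 and 1; without the 2 arrays day 37 against steady state gave 481, of which 204 were shared, and the second MHCII difference 1. Leaving out each array in turn gave 1127 to 1243, 725 to 940, 398 to 528 and 249 to 341 at days 1.5, 5, 10 and 37; 37 to 53, 28 to 34 and 53 to 96 for MHCII high against low; 434 to 484, 108 to 150 and 49 to 111 between days; and 3 to 7 and 0 to 2 for the MHCII differences. The extremes beyond 1.5 times were 37 without day 1.5 MHCII high replicate 2, 28 without day 5 MHCII low replicate 3, 111 without day 10 MHCII low replicate 3, 3 without day 1.5 MHCII high replicate 1 or 2 or any day 5 array, and 2 without day 10 MHCII high replicate 1. Of 127 gene list shifts 61 held with an estimated correlation, and fry gave 136, of which 112 were shared. The median of neutrophil markers, MHCII high against low at day 10, turned to 0.18 without the 7 arrays, and that of lipid-handling genes, MHCII difference from day 5 to 10, to 0.0302 without day 10 MHCII low replicate 3 (-0.127 to 0.0302 over the arrays left out in turn). Except for the minimum fold, the cause was not tested. Over all alternatives, named genes kept their side of the threshold in 13776 cases, fell below it in 247, passed it in 132 and reversed in 0. A change of sign counted as a reversal only if the gene was called in either fit. Genes called in neither fit may have changed sign among the 13776. List medians kept within their spread in 2644 cases and moved in 112. The kept cases include those of the 47-array table, which could not differ. With replicate number as a block over all groups the counts were 1144, 741, 404, 259, 59, 42, 68, 462, 122, 79, 5 and 0 in the order above, and with a replicate block within each day 55, 48, 81, 5 and 0 for the MHCII comparisons. Of the 5 called in the first MHCII difference within each day (1 higher, 4 lower) 4 were shared. Numbers were taken to pair the arrays at day 5 only. For MHCII high against low at day 5 the block changed no other call of a named gene or list than those given in the report. For the MHCII differences the block changed no other call of a named gene than those given, and lists were not tested with it. At the other days it left Bhlhe41, Mmp8 and Egln3 at day 1.5 and Dpp4 at day 10 outside the calls, and brought in Gpnmb at day 1.5 and Cd209d, Birc5 and Fabp4 at day 10. Signal over background limits what can be seen: 11725 of 19938 genes passed the filter, and differences of dim genes are compressed.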

Other observations

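Tests of gene lists in this part belong to the same family as those of the report, and its named genes outside the naming rule (Cfb, C4b and Igf1 at days 1.5 and 5, Pdgfc and Igf1 at day 10, and Arg1 and Mgl2 at day 37) were chosen after their values were seen. Complement genes, whose products tag debris for uptake, rose in 2 of 8 at day 10 (2 over the list alone; camera adjusted p = 0.0018, adjusted p = 0.165 with an estimated correlation) and in 3 of 8 at day 37 (3 over the list alone; 0.00351, adjusted p = 0.203 with an estimated correlation). Cfb, a factor of the alternative pathway, was higher by 2.33 ± 0.26, 2.66 ± 0.26, 2.86 ± 0.26 and 2.90 ± 0.31 (log2, SE) at days 1.5, 5, 10 and 37, and C4b by 1.49 ± 0.15, 1.85 ± 0.15 and 2.22 ± 0.17 at days 5, 10 and 37 after -1.19 ± 0.15 at day 1.5. Growth and neurotrophic factor genes rose in 2 of 11 at day 37 (2 over the list alone; 0.0361, adjusted p = 0.231 with an estimated correlation): Pdgfc, a mitogen of mesenchymal cells (2.31 ± 0.33), and Igf1 (1.24 ± 0.11). At day 10 they stood at 2.42 ± 0.28 and 1.21 ± 0.09, and Igf1 stood at -0.90 ± 0.10 at day 1.5 and 0.67 ± 0.10 at day 5.

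Iron and haem genes rose in 2 of 10 from day 5 to day 10 (2 over the list alone; camera adjusted p = 6.29e-04, adjusted p = 0.0689 with an estimated correlation), namely ferroportin, Slc40a1 (1.17 ± 0.21), and ceruloplasmin, Cp (1.04 ± 0.17). Alternative activation genes went both ways at day 1.5, with 3 of 11 higher and 2 lower (3 and 2 over the list alone; 0.335): Arg1 stood at 6.61 ± 0.18 and Mgl2 at -5.38 ± 0.22, against 0.12 ± 0.21 and 0.09 ± 0.25 at day 37.

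The Y-linked genes Kdm5d, Eif2s3y and Uty were above log2 6 in 7 arrays: steady state replicate 2, the day 5 MHCII high and low replicates 3, day 10 MHCII high replicates 2 and 3, and day 10 MHCII low replicates 1 and 2. Xist stood between 8.75 and 9.56 in these and between 9.51 and 10.73 in the others, where Kdm5d was at most 4.94, Eif2s3y at most 3.89 and Uty at most 4.45. The first principal component held 38.4% of the variance and the second 15.1%.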
